A study of Mus musculus with 2 samples.

How the data were processed

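The deposited matrices held raw UMI counts per gene and barcode, whole numbers without normalisation, as their values show. Per the submitters' processing notes, the authors used Cell Ranger (no version given) and Scanpy 1.9.5 with genome build GRCm39 (mm39); which step each tool served, and the alignment settings, are not given in the sources used here. Per the labels, the libraries were 10x Genomics 3' libraries. Both matrices listed the same 32285 mouse genes, 78 of their symbols occurring more than once. Chromosome names came from GENCODE release M21 by gene identifier, which matched 32158 genes (99.6%). That annotation serves another build, so no coordinates are printed.

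Cells with fewer than 500 genes or more than 15% mitochondrial UMIs were left out, 645 barcodes in library 1 and 308 in library 2. Doublets were scored per library with Scrublet. Its automatic threshold was 0.312 in library 1 and 0.4996 in library 2, and the lower one was used for both, which left out 72 (1.38%) and 38 (0.906%) cells. Each cell was scaled to 10000 UMIs and log-transformed, and 2359 of 2500 highly variable genes were kept after leaving out Y genes and every gene of the fixed lists. Clustering used 30 principal components, 15 neighbours and the Leiden method at resolution 1, which gave 19 clusters. A cluster took the type with the most fixed markers detected in at least 20% of its cells at 20% or more of the highest cluster's level, given at least 3. It stayed unnamed when its 10 leading genes held more markers of another type, or when it was shallow and they held none of its own. The 2 libraries shared 9 barcodes, and their summed counts and cluster sizes differed by more than sampling (chi-square over degrees of freedom 89.1 and 55.0), so they were treated as separate samples. T-like cells with at least 1 Cd4 UMI and none of Cd8a or Cd8b1 formed the CD4 gate, and the opposite the CD8 gate.

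Shares of cells were read after each cell was thinned at random to 2000 UMIs, so that all cells had the same depth. Cells with fewer UMIs were left out and counted. A cell was Y-positive with at least 1 UMI of the 4 Y genes and Y-null with none. Null shares were compared with those of 200 panels of 4 autosomal genes, each drawn from the 50 genes nearest in CPM to its Y gene. Draws of the thinning gave different calls, so 5 further draws were made after the data were seen.

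For the comparisons, UMI counts were summed per library and cell group and fitted with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr), with the library as a block because both sums of a library come from the same suspension. Each comparison had 4 sums and 1 residual degree of freedom, and the interaction had 8 sums and 3. The spread was shared across genes by empirical Bayes. In the main fits the prior degrees of freedom were infinite, except for CD4 against CD8 T cells (14.05) and the interaction (43.83). Where they were infinite, a gene's own disagreement between the libraries did not enter its p-value. P-values were adjusted by Benjamini and Hochberg over all genes tested, at a threshold of 0.05. Gate genes were left out of the comparison they defined. Gene lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 and again with the correlation estimated, when at least 4 members were tested. There were 23 lists. Counts of list genes are given over all genes tested and adjusted over the list alone. Values per library are log2 ratios of CPM with a prior count of 2. Where a group had no UMI of a gene in either library, the fold was computed against a floor of 3 counts over the group, and where it had 1 to 3 UMIs the ratio is given with an exact counting interval.

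The lists, cell type markers, tests and most alternatives were fixed before the data were examined, and so was the rule for named genes. The rule took the Y panel and Xist, then the 12 highest and 12 lowest genes past the threshold with the same sign in both libraries and a mean of at least 20 CPM, leaving out receptor and immunoglobulin segments and mitochondrial, ribosomal and predicted genes, and then up to 4 members of each list past the threshold. The alternatives were DESeq2 1.42.0, no filter on low counts, no library block, doublets kept, other thinning depths (1000 and 5000 UMIs), a gate or Y status at 2 UMIs, Y genes left out singly, other Leiden resolutions (0.5 and 2), stricter cell filters (1000 genes, 10% mitochondrial UMIs) or none, housekeeping-like panels, all classes in the fit, and each library left out.

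Scripts were tested on simulated data drawn from the real means. For the comparisons the dispersion was set at 0.01 rather than estimated, with the same changes in both libraries. The shares recovered and the false calls hold for that setting only. In the CD4 against CD8 comparison, 71% of genes changed by 2-fold and 94% of those changed by 4-fold were recovered, with 5 false calls. For Y status the shares were 66.7% and 97% in CD8 T cells with 4 false calls, and 27.6% and 92% in CD4 T cells with 1 false call. For Foxp3 status they were 41.8% and 95.9% with 4 false calls, and for tumour-like against macrophage-like cells 69.4% and 94.9% with 6. In panels standing in for the Y genes in CD8 T cells of library 2 at 20000 UMIs, a simulated loss in 5% of cells raised the null share by 4.75 points on average and one in 10% by 10.1 points, and no loss by 0.180 points.

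Clustering and shares were computed in Python 3.11.15 with scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2 and scikit-learn 1.9.0, and fits in R 4.3.3. Figures were drawn with matplotlib 3.10.9.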

Results

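Single-cell RNA-seq was run on tumours grown under the skin of C57Bl/6J mice from MB49 clone 5, a derivative of the mouse bladder carcinoma line MB49 that has lost the Y chromosome (LOY). The labels give 4 mice, 100000 tumour cells injected and a tumour volume of 500 mm³ at collection. Leukocytes taken by CD45 selection were separated into CD4, CD8 and CD11b fractions, pooled in equal parts, and added to a like number of live CD45-negative cells. The series has 1 group of 2 libraries in 1 batch, and each library was a 10x Genomics 3' library. Library 1 held 5873 barcodes and 94890484 UMIs, and library 2 held 4503 barcodes and 74680641 UMIs. After filtering, 5156 and 4157 cells remained in libraries 1 and 2, with a median of 14390 and 12855 UMIs per cell. The labels do not say which of the 4 mice are in which library, so the spread between these 2 libraries may be technical. No p-value covers more than that spread. In most edgeR fits it was pooled over genes, so a gene whose libraries disagree can still pass. Fold changes are log2 values from UMI counts summed per library and cell group, with n = 2 libraries per group. Many of them are given with a standard error (SE), computed as the absolute log2 fold change over the square root of the quasi-likelihood F statistic. This SE carries the spread shared across genes, so it can be small where the libraries of a gene disagree. Intervals of shares are exact Clopper-Pearson 95% intervals and cover counting error only.

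T cells made up the largest class in both libraries, followed by macrophages and monocytes and then by neutrophils. The T-like class held 51.6% of cells in library 1 (50.2% to 52.96%, 2660 cells) and 61.9% in library 2 (60.4% to 63.4%, 2575 cells). Macrophage- and monocyte-like cells, led by Mmp12, C1qa and C1qb, took 17.3% and 20.8%. Neutrophil-like cells with S100a8 and S100a9 took 9.83% and 10.7%, and dendritic-like cells with Xcr1, Clec9a or Ccl22 took 4.21% and 4.16%. Tumour-like cells, 2 clusters led by the epithelial keratins Krt8 and Krt18, took 5.33% (275 cells) and 1.88% (78 cells). Only 3 and 4 of the fixed tumour markers passed in these clusters, and the epithelial genes Epcam, Cldn4 and Cldn7 stood at 0 CPM in both. Within the T-like class, a cluster of 881 cells was led by Ikzf2, Ctla4 and Il2ra, and a cluster of 147 cells by Penk, Ccl1, Tnfsf11 and Tnfsf8. Fibroblast-like cells numbered 101 and 8, and endothelial-like cells 18 and 6. A shallow cluster with the naive T cell genes Lef1, Satb1 and Bach2 among its leading genes held 484 cells in library 1 and 9 in library 2, and was left unnamed. Cd3e was detected in 72.4% and Cd4 in 50.7% of its cells. The gated T cells below, and their Foxp3 shares, therefore lack the T cells of this cluster, most of them from library 1. At Leiden resolution 0.5 no cluster stayed unnamed, and the T-like shares were 61.0% and 62.2%. The lower T-like share of library 1 thus depends on the naming rule. The sort and the mixing set the shares of all classes, so they were not compared between groups.

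The series title concerns loss of Y in cancer cells together with T cells, so the first question was how far each class expressed Y genes. T cells carried Y transcripts and tumour cells carried almost none. The Y panel, the 4 broadly expressed Y genes Ddx3y (ENSMUSG00000069045), Eif2s3y (ENSMUSG00000069049), Kdm5d (ENSMUSG00000056673) and Uty (ENSMUSG00000068457), stood at 287 and 228 counts per 1000000 UMIs (CPM) in T-like cells of libraries 1 and 2, and at 5.41 and 6.98 CPM in tumour-like cells. Uty, a member of the KDM6 family, was higher in T-like than in tumour-like cells by a log2 fold change of 5.78 (SE 0.245, adjusted p = 1.31e-119 in edgeR). Eif2s3y, a translation initiation factor subunit, was higher by 6.02 (SE 0.289), Kdm5d, a histone demethylase, by 5.11 (SE 0.410) and Ddx3y, an RNA helicase, by 4.64 (SE 0.229). All 4 genes passed the test in that direction, and the panel's mean log2 fold change was 5.39. As a list the panel was higher in T-like cells (camera, adjusted p = 1.34e-04; adjusted p = 0.557 with an estimated correlation). Host myeloid cells carried the panel as well. Neutrophil-like cells had the highest level of the 6 groups plotted, 566 and 462 CPM, macrophage- and monocyte-like cells had 324 and 272 CPM, and dendritic-like cells had 214 and 170 CPM. The X-linked transcript Xist gave no UMI in tumour-like cells (upper limits of exact Poisson 95% intervals 0.377 and 1.29 CPM) and 2 UMIs in the T-like cells of each library.

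Counted per cell, with each cell thinned to 2000 UMIs, 45.6% of T-like cells in library 1 (43.6% to 47.5%) and 38.8% in library 2 (36.9% to 40.8%) had a Y panel UMI. Tumour-like cells, the background for host cells, gave 1.82% (0.595% to 4.21%, 5 of 274 cells) and 1.64% (0.0410% to 8.80%, 1 of 61 cells). Thinning left out 41 and 37 T-like cells and 1 and 17 tumour-like cells. Before thinning, 93.4% and 87.2% of T-like cells and 8.0% and 12.8% of tumour-like cells had a Y panel UMI, at median depths of 16308 and 11955 UMIs for T-like and 30201 and 32935 UMIs for tumour-like cells. At 2000 UMIs the share was 44.8% and 39.0% in macrophage- and monocyte-like cells, 53.7% and 49.0% in neutrophil-like cells and 30.2% and 31.8% in dendritic-like cells. CD4 T cells reached 46.7% and 48.7%, and CD8 T cells 44.9% and 37.1%. The difference between T-like and tumour-like cells was 40.5 percentage points (SD 4.61, n = 2 libraries).

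**Figure D1:**
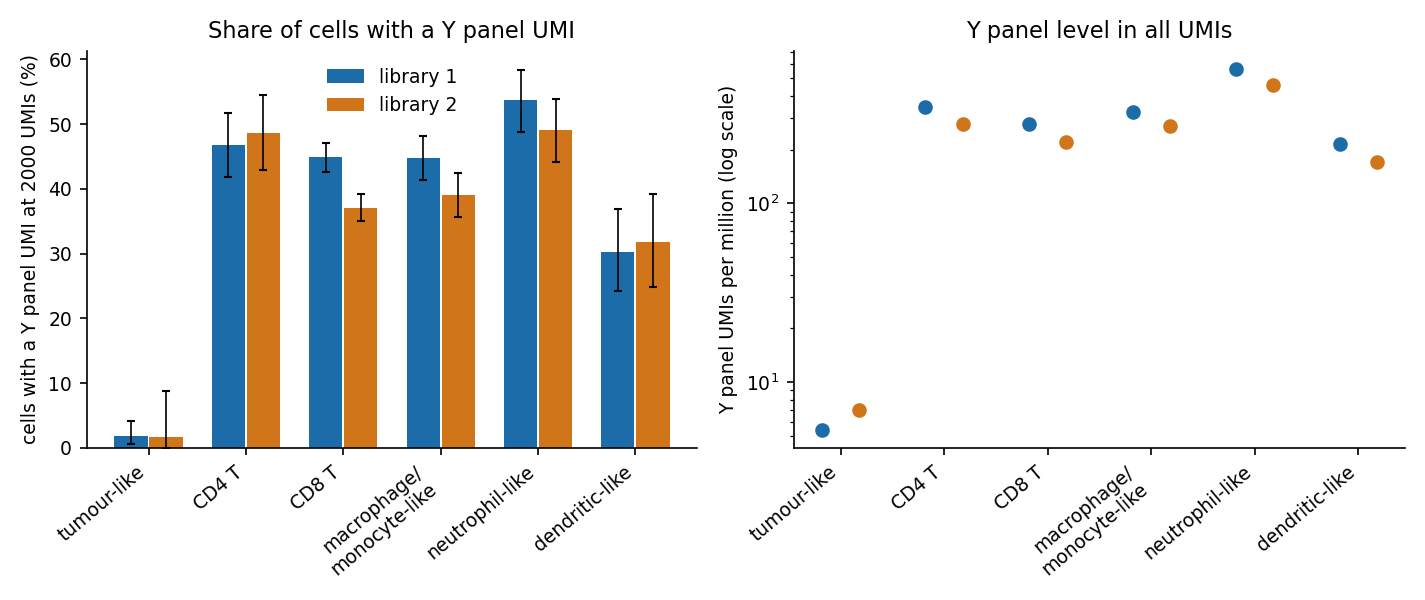
Share of cells with a Y panel UMI at 2000 UMIs per cell, in percent with exact 95% intervals (left), and Y panel level in counts per 1000000 UMIs on a log axis (right), for 6 cell groups and both libraries. Tumour-like cells sit at 5.41 and 6.98 CPM, and the host groups between 170 and 566 CPM.

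CD4 and CD8 T cells of the T-like clusters, gated on UMIs of Cd4 or of Cd8a and Cd8b1, were compared to describe the T cell programmes of these tumours. CD4 T cells carried more T helper and regulatory T cell genes, and CD8 T cells carried more cytotoxic genes. The comparison rested on 423 and 304 CD4 T cells (median 10073 and 8048 UMIs) and 2020 and 2054 CD8 T cells (median 17913 and 12846 UMIs). The regulatory T cell factor Foxp3 (ENSMUSG00000039521) was higher in CD4 T cells by 6.60 (SE 0.126, adjusted p = 4.95e-15 in edgeR). The granzyme gene Gzmf (ENSMUSG00000015441) was lower in CD4 T cells, at -8.29 (SE 0.152, adjusted p = 4.75e-15 in edgeR). Of 13330 genes tested, 2440 were higher and 2545 lower in CD4 T cells, and 4976 of these 4985 genes had the same sign in both libraries.

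Cytokine genes marked the CD4 T cells. Il13, a type 2 cytokine, was higher by 9.35 (SE 0.219) and Il10, an inhibitory cytokine, by 6.27 (SE 0.115). Il4 had no UMI in CD8 T cells of either library, which makes it at least 1292-fold higher in CD4 T cells over a floor of 3 counts. Il5 had 2 UMIs in CD8 T cells and was higher in CD4 T cells by a ratio of 844 (231 to 7016, counting interval). The B cell helper ligand Cd40lg followed at 6.20 (SE 0.261), the TGF-beta activating surface protein Lrrc32 at 6.12 (SE 0.204), and the integrin chains Itgb8 at 5.15 (SE 0.150) and Itgae at 4.69 (SE 0.224). Maf, a transcription factor of helper cells, was higher by 4.94 (SE 0.0817), Klrg1 by 4.93 (SE 0.107) and the interleukin 33 receptor Il1rl1 by 4.68 (SE 0.146). Tmtc2 (5.71), Plcb4 (5.26), the interferon-induced GTPase Iigp1 (5.24) and the galectin Lgals7 (5.22) were also among the highest. The costimulatory receptors Tnfrsf4 (1.91) and Icos (1.84) and the ligand Cd274 (1.35) were higher by smaller amounts.

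On the CD8 side stood granzymes and some receptor genes. Gzma was at -5.75 (SE 0.381), with library values of -7.65 and -3.99, and Gzmk at -4.80 (SE 0.325), with -7.26 and -3.43. The lectin-like receptors Klre1 (-5.47, SE 0.134) and Klrk1 (-4.94, SE 0.160) were lower in CD4 T cells, as were the receptors Cd244a (-4.37) and Cd160 (-4.17), the adhesion molecule Crtam (-3.42, with library values of -2.46 and -5.52) and the chemokine Ccl5 (-2.24). Gipc2 (-5.34) and Bend4 (-4.96) were among the 12 lowest genes. Rgs8 had 3 UMIs in CD4 T cells and was higher in CD8 T cells by a ratio of 126 (43.1 to 612). The haemoglobin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt also came among the 12 lowest (-5.47 to -5.08), but single cells carried much of them. One CD8 T cell held 3555 of the 4128 Hbb-bs UMIs of CD8 T cells in library 1 and another held 5809 of 15860 in library 2, while 6.83% and 8.76% of CD8 and 7.33% and 8.88% of CD4 T cells had an Hbb-bs UMI. With the unnamed cluster included, Hbb-bt turned to 0.55.

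**Figure D2:**
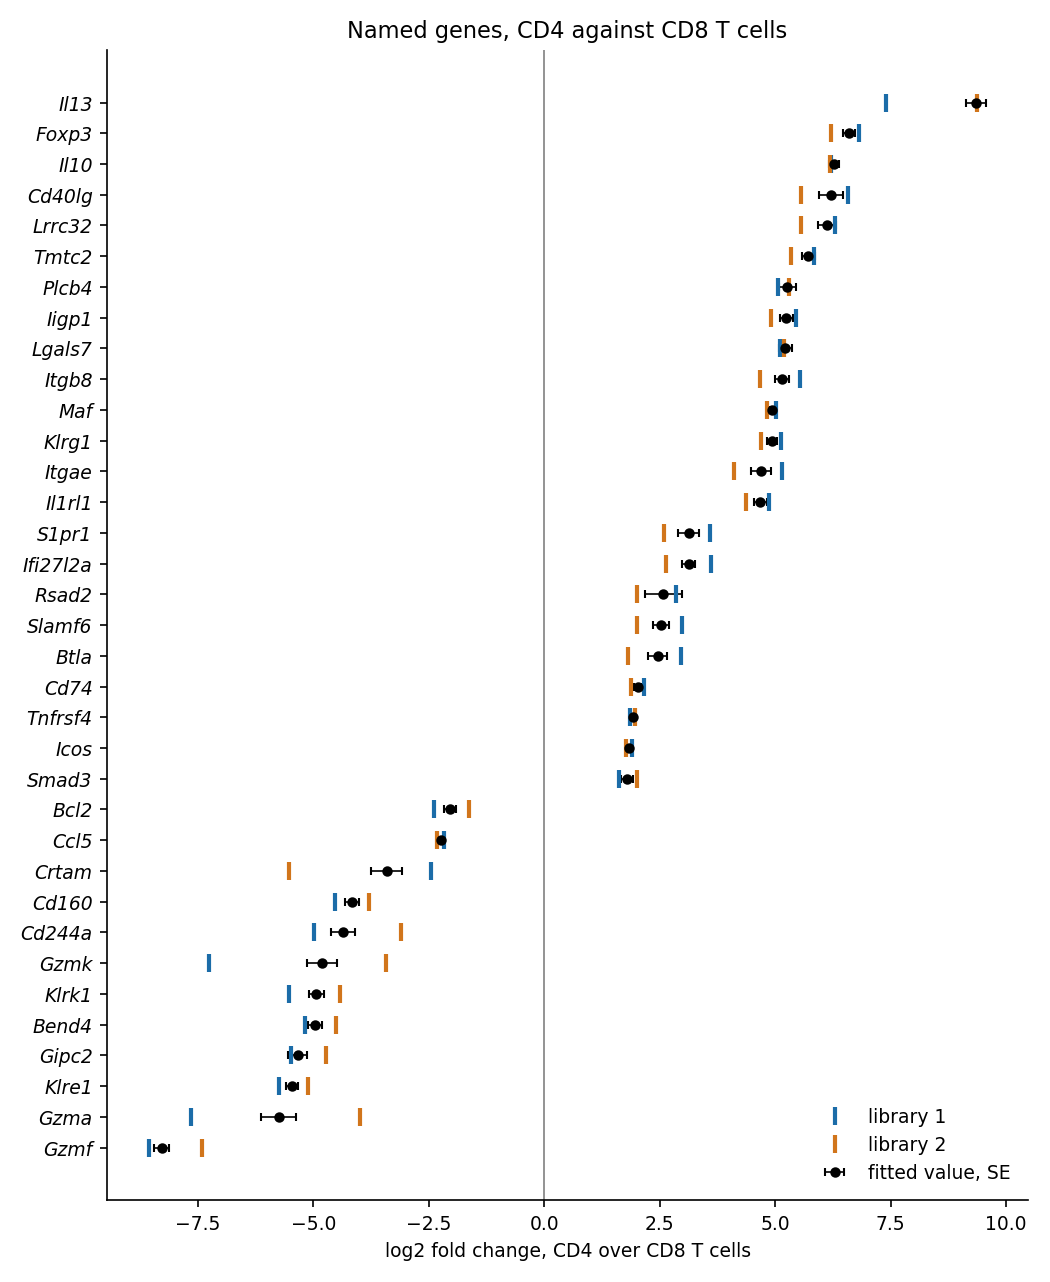
Log2 fold change of CD4 over CD8 T cells for genes named in the text with an absolute value above 1.5 (points with SE) beside the value in each library (coloured ticks), leaving out haemoglobin genes and genes with 3 or fewer UMIs in a group. The values run from -8.29 for Gzmf to 9.35 for Il13.

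Fixed gene lists gave the same division. All 15 tested members of the regulatory T cell list were higher in CD4 T cells (median 2.45; camera, adjusted p = 6.47e-62; adjusted p = 0.480 with an estimated correlation). Of 14 T helper genes 11 were higher, 2 lower and 1 did not pass, with a median of 3.12, against 12 higher adjusted over the list alone. Of 18 cytotoxic genes 16 were lower, 1 was higher and 1 did not pass, with a median of -2.63, and the counts were the same adjusted over the list alone. Interferon response genes were mostly higher in CD4 T cells, 20 of 24 with none lower (21 and 1 adjusted over the list alone), such as Ifi27l2a (3.12) and Rsad2 (2.57). Naive and memory genes went the same way in 9 of 12, including S1pr1 (3.12) and Slamf6 (2.52), while the survival gene Bcl2 (-2.05) was higher in CD8 T cells. MHC class II genes were higher in 5 of 7, led by Cd74 (2.02), and TGF-beta signalling genes in 8 of 12, such as Smad3 (1.80). Costimulation genes were higher in 7 of 10 and checkpoint ligands in 5 of 11, with 2 and 3 lower. Proliferation genes were lower in CD4 T cells in 18 of 22 with none higher (19 adjusted over the list alone), with a median of -0.40, among them Top2a (-0.56), Pclaf (-0.60) and Stmn1 (-0.52). Oxidative phosphorylation genes were lower in 12 of 19 (14 adjusted over the list alone), by a median of -0.27. Checkpoint receptors split, 7 higher, such as Btla (2.45), and 8 lower, and camera gave no call (adjusted p = 0.2002). For the p53 list the median (-0.26) and the mean (0.12) differed in sign, and camera gave no call. In all, 12 lists passed camera at its preset correlation and 0 with an estimated correlation. Uty (0.29, SE 0.0766) and Ddx3y (0.27, SE 0.0932, with library values of 0.11 and 0.47) were slightly higher in CD4 T cells, and Kdm5d and Eif2s3y did not pass. DESeq2 called 2515 genes, and 2072 were called without the library block, all of them among the 4985.

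Within the CD4 gate, cells with a Foxp3 UMI at 2000 UMIs were set against those without, to describe the regulatory T cells among the sorted CD4 cells. Foxp3-positive cells carried more of the receptors and factors of activated regulatory T cells. Cells without a Foxp3 UMI at that depth carried more helper cytokine and memory genes. Foxp3 was seen in 36.9% (32.2% to 41.7%, 153 of 415 cells) and 33.7% (28.3% to 39.3%, 101 of 300 cells) of CD4 T cells, against 0.399% and 0.343% of CD8 T cells. Before thinning, the shares were 68.6% and 55.3% in CD4 and 1.09% and 1.51% in CD8 T cells. Median depths were 10073 and 8048 UMIs in CD4 and 17913 and 12846 UMIs in CD8 T cells. Part of the cells called Foxp3-negative at 2000 UMIs therefore carry Foxp3 transcripts, and the split does not separate cells with and without Foxp3. Thinning left out 8 and 4 CD4 and 14 and 15 CD8 T cells. Ikzf2 (ENSMUSG00000025997), a factor that stabilises regulatory T cells, was higher in Foxp3-positive cells by 0.86 (SE 0.0825, adjusted p = 4.47e-22 in edgeR). The inhibitory receptor Ctla4 (ENSMUSG00000026011) was higher by 0.60 (SE 0.0931, adjusted p = 2.39e-08 in edgeR) and the costimulatory receptor Tnfrsf9 by 0.61 (SE 0.0958). In total 131 genes were higher and 161 lower among 5467 tested.

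Other genes higher in Foxp3-positive cells were Klrg1 (1.09, SE 0.175), Gzmb (0.92, SE 0.108), Cd27 (0.76, SE 0.188), the integrin Itgav (0.69, SE 0.105), Vim (0.47, SE 0.109), Iigp1 (1.17, SE 0.251, with library values of 0.45 and 1.81) and Lrrc32 (1.68, SE 0.361). Cep112 was higher by 1.43 (SE 0.291) and Cxcl2 by 1.10 (SE 0.288), the latter at -0.02 in library 1 and 2.16 in library 2. Helper ligands and cytokines fell on the other side. The chemokine Ccl1 had no UMI in Foxp3-positive cells and was at least 46.6-fold lower there over a floor of 3 counts, and the survival gene Bcl2 was at least 13.0-fold lower. Tnfsf8 was higher in Foxp3-negative cells by a ratio of 257 (45.9 to 10177), Il13 by 45.1 (7.88 to 1805), Csf2 by 24.2 (4.13 to 978) and Cd40lg by 9.18 (2.96 to 46.0), each with 3 or fewer UMIs in Foxp3-positive cells. The memory factor Tcf7 had a ratio of 21.2 (5.67 to 178), Klrd1 one of 28.6 (7.73 to 240) and Tbc1d4 one of 25.7 (8.61 to 126). Tnfsf11, the RANK ligand, was lower in Foxp3-positive cells at -3.58 (SE 0.2997), Ifng at -2.46 (SE 0.379), Btla at -2.19 (SE 0.431, with library values of -2.22 and -1.41), Bach2 at -2.16 (SE 0.293), Itgb1 at -1.87 (SE 0.226), the homing receptor Ccr7 at -1.85 (SE 0.289) and Pdcd1 at -1.01 (SE 0.224).

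**Figure D3:**
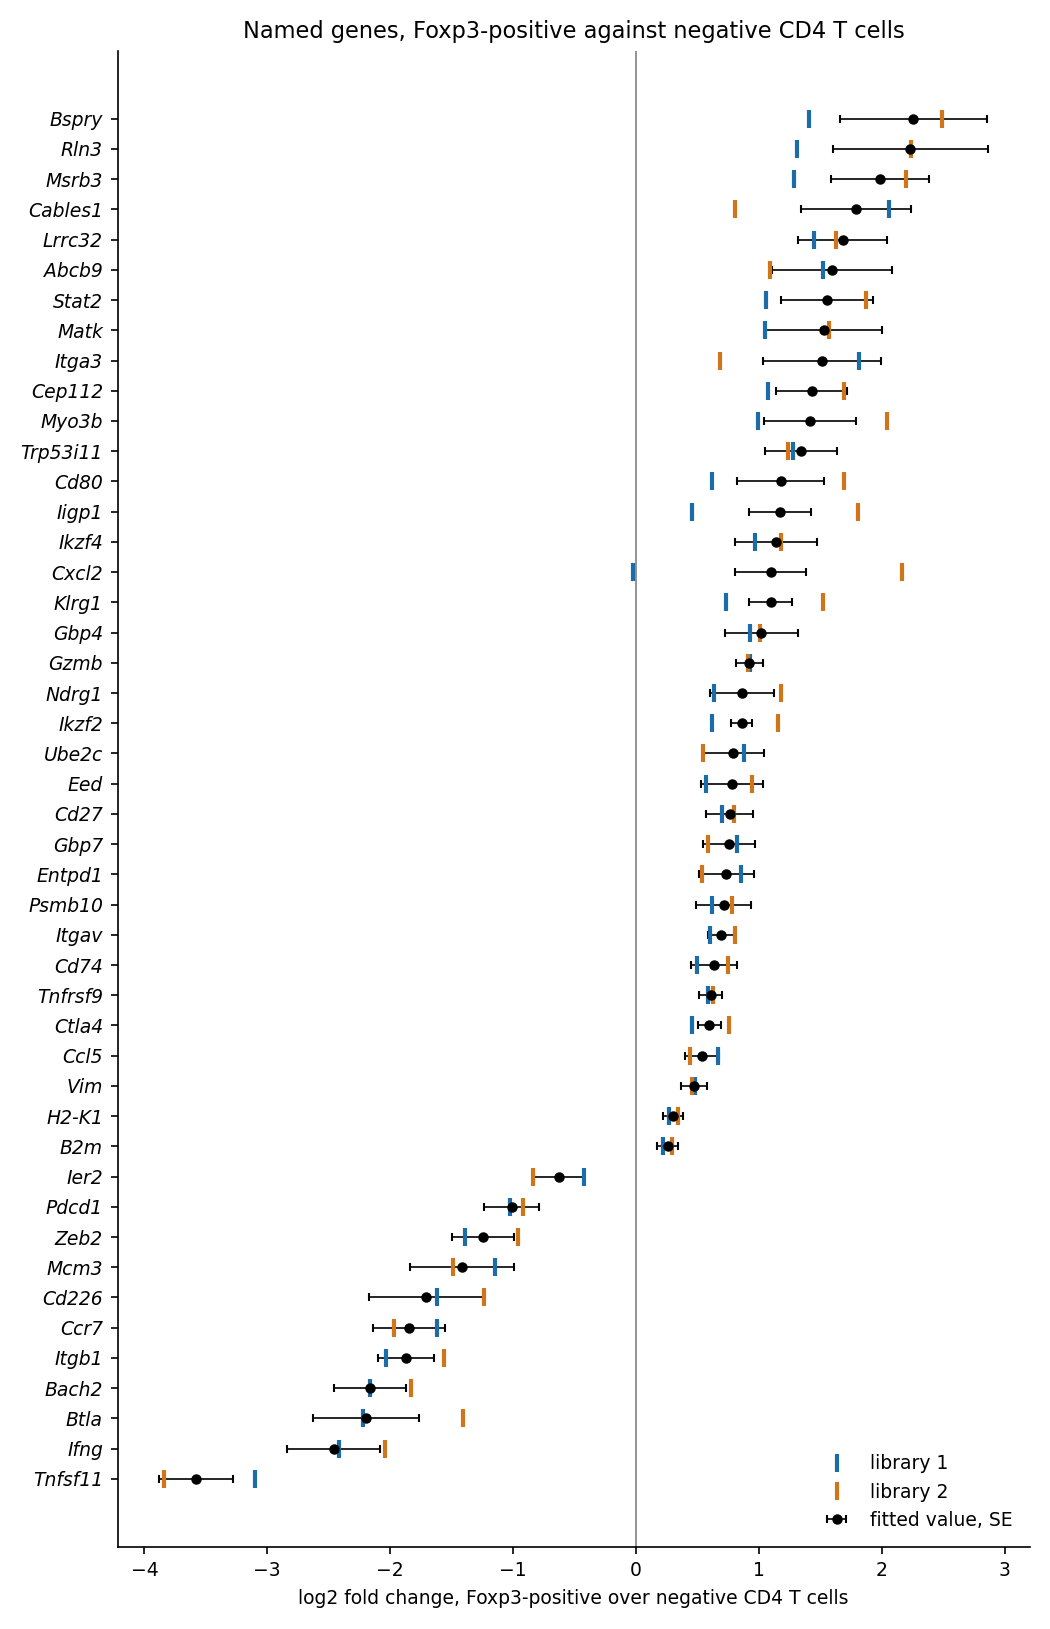
Log2 fold change of Foxp3-positive over Foxp3-negative CD4 T cells for named genes past the threshold (points with SE) beside the value in each library (coloured ticks), leaving out genes with 3 or fewer UMIs in a group. Tnfsf11 lies at -3.58 and Lrrc32 at 1.68.

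Of 14 regulatory T cell genes other than Foxp3, 10 were higher in Foxp3-positive cells and none lower (11 adjusted over the list alone), with a median of 0.60 (camera, adjusted p = 7.07e-18; adjusted p = 0.587 with an estimated correlation). Of 9 T helper genes 5 were lower, 1 was higher and 3 did not pass, with a median of -2.46. Naive and memory genes were lower in 5 of 11 with none higher (7 and 1 adjusted over the list alone), with a median of -1.05. Interferon response genes were higher in 4 of 15 (6 adjusted over the list alone), such as Stat2 (1.55) and Gbp7 (0.76), and MHC class I genes in 3 of 15 (4 adjusted over the list alone), such as H2-K1 (0.30). In 5 further draws of the thinning, 4 to 10 regulatory T cell, 4 to 7 naive and memory, 0 to 3 interferon response and 0 to 2 MHC class I genes passed, and Stat2 passed in none, at 0.12 to 0.66. Costimulation genes were higher in 5 of 9 and lower in 2, with a median of 0.48 and a mean of -0.16, and camera called the list higher (adjusted p = 0.00152; adjusted p = 0.587 with an estimated correlation), while 4 to 7 of its genes passed in the further draws. In total 6 lists passed camera at the preset correlation and 0 with an estimated one. Of the Y panel, Ddx3y, Uty and Eif2s3y were tested and none passed. DESeq2 called 25 genes and a fit without the library block 59, all among the 292. In the further draws 141 to 343 genes were called, of which 118 to 189 were among the 292, and 27 of the 59 named genes passed in every draw, Ctla4, Tnfrsf9, Ikzf2, Klrg1, Gzmb, Ccl1, Tnfsf8, Il13, Ifng and Pdcd1 among them.

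How many host cells lacked Y transcripts beyond what depth alone gives was measured against autosomal gene panels of the same level. At 2000 UMIs, Y-null T cells and macrophages were within a few percentage points of the share such panels gave, and Y-null neutrophils lay further above it. Y-null cells made up 53.3% (48.3% to 58.1%) and 51.3% (45.5% to 57.1%) of CD4 T cells, against panel medians of 48.2% and 51.7%. Among CD8 T cells they made up 55.1% (52.9% to 57.3%) and 62.9% (60.7% to 65.0%), against 55.8% and 58.5%, and among macrophage- and monocyte-like cells 55.2% and 61.0%, against 55.2% and 56.4%. The mean difference from the panels was 2.36 points in CD4 T cells, 1.88 points in CD8 T cells and 2.35 points in macrophages, and with panels matched on CPM over both libraries it rested on 1 library in each: 5.06 and -0.333 points in CD4, -0.648 and 4.41 points in CD8 and 0.0590 and 4.64 points in macrophages, for libraries 1 and 2. At most 18 of 200 panels reached the Y-null share in the higher library of each of these groups, and at least 100 of 200 did in the other library. With panels matched within each library, a choice made after the data were seen, all of these differences were above 0, at 4.34 and 1.33 points in CD4 (7 and 52 of 200 panels reached the share), 2.32 and 1.32 points in CD8 (3 and 11) and 1.53 and 2.62 points in macrophages (32 and 13). Neutrophil-like cells lay 5.51 and 9.95 points above panels matched over both libraries (36 and 5 of 200), and at 5000 UMIs, where 26 of 107 and 33 of 129 cells were null, 10.3 and 11.6 points above (7 and 0 of 200). Deeper cells left fewer null cells to chance. At 20000 UMIs, a depth added after the data were seen, 20 of 454 macrophages in library 1 (4.41%, 2.71% to 6.72%) and 51 of 522 in library 2 (9.77%, 7.36% to 12.6%) had no Y panel UMI, against panel medians of 0.881% and 0.958%. Among CD8 T cells 20 of 818 (2.44%) in library 1 and 55 of 584 (9.42%) in library 2 had none, against 1.96% and 2.40%. Of dendritic-like cells, 11 of 170 (6.47%) and 13 of 148 (8.78%) had none, against 3.53% and 5.41%. These dendritic shares were reached by 23 and 24 of 200 panels. That depth left out 440 and 341 macrophages and 1202 and 1470 CD8 T cells. No macrophage of either library lacked a UMI of all 4 X-linked homologues (Ddx3x, Eif2s3x, Kdm5c and Kdm6a) at that depth. This allows shares of up to 0.661% and 0.575% (3 counts of the total). Fewer macrophages also lacked the homologues at 2000 UMIs, 35.1% and 41.5% against 55.2% and 61.0% for the Y panel. Their level alone may therefore give fewer null cells, so they are no matched control. In library 2, 0.685% of CD8 T cells and 2.03% of dendritic-like cells lacked them at 20000 UMIs.

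**Figure D4:**
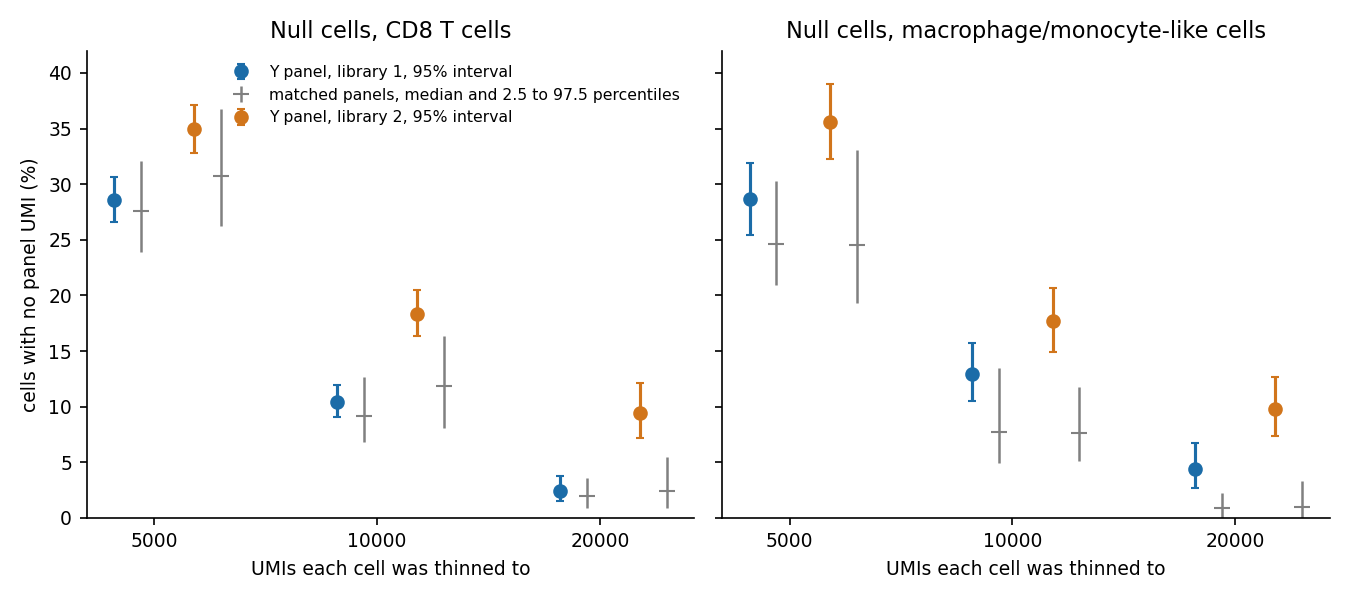
Share of CD8 T cells (left) and macrophage- and monocyte-like cells (right) without a Y panel UMI after thinning to 5000, 10000 or 20000 UMIs, in percent with exact 95% intervals, for both libraries. Grey marks show the median and the central 95% of 200 matched panels, with medians of 0.881% and 0.958% for macrophages at 20000 UMIs.

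Y-null T cells were set against Y-positive ones at 2000 UMIs to see which genes go with the Y transcripts. Before thinning, 90.8% and 86.8% of CD4 and 94.2% and 88.0% of CD8 T cells had a Y panel UMI, so most cells called null at this depth carry Y transcripts, and the split does not separate cells with and without the chromosome. Few genes passed in CD4 T cells, with some cell division genes among those higher in Y-null cells and the chemokine Ccl5 among those lower. The chromatin protein gene Hmgb2 (ENSMUSG00000054717) was higher in Y-null cells by 0.69 (SE 0.119, adjusted p = 2.10e-05 in edgeR), and Ccl5 (ENSMUSG00000035042) was lower, at -0.82 (SE 0.141, adjusted p = 2.10e-05 in edgeR). Sums of 221 and 154 null and 194 and 146 positive cells were compared, and 11 genes were higher and 6 lower among 5371 tested. The microtubule regulator Stmn1 was higher by 0.79 (SE 0.182), the replication factor Pclaf by 0.89 (SE 0.219), the mitotic genes Nusap1 by 1.47 (SE 0.374) and Cenpf by 1.65 (SE 0.375), and the histone genes Hist1h2ap by 0.73 (SE 0.179) and H2afz by 0.49 (SE 0.118). Ran (0.63), the enkephalin precursor Penk (0.76), Il13 (1.58) and Cisd3 (2.05) were also higher. The kinase gene Camk4 (-0.62), Zfp36l2 (-0.72), Tsc22d2 (-0.95) and the heat shock gene Hspa1b (-1.48) were lower, but Tsc22d2 turned to 0.17 at 1000 UMIs and Hspa1b to 1.01 at 5000 UMIs. Pclaf was at 0.60 in library 1 and 1.40 in library 2, Hist1h2ap at 0.95 and 0.39, Tsc22d2 at -1.11 and -0.61, and Hspa1b at -2.02 and -0.45. Proliferation genes were higher in 5 of 20 with none lower (10 adjusted over the list alone), with a median of 0.61 (camera, adjusted p = 4.80e-14; adjusted p = 0.964 with an estimated correlation). Oxidative phosphorylation genes had a median of 0.29 with none of 19 passing (camera, adjusted p = 3.67e-05; adjusted p = 0.964 with an estimated correlation). Chemokine genes had a median of -0.74, with 1 of 7 lower (3 adjusted over the list alone; camera, adjusted p = 0.00186; adjusted p = 0.964 with an estimated correlation), and the library medians were 0.37 and -0.89. None of 14 checkpoint receptor genes and none of 15 regulatory T cell genes passed.

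These CD4 calls depended on the fit and on the draw of the thinning. DESeq2 called 0 genes, with 28 at an unadjusted p under 0.05, a fit without the library block called 0 with 178, and edgeR with the block had 496 at that level. In 5 further draws 4 to 85 genes were called, 2 to 9 of them among the 17, and Hmgb2 passed in 5 draws, Hist1h2ap and H2afz in 4, Ran and Ccl5 in 3, and Il13, Cenpf, Pclaf and Cisd3 in 0. Cenpf, Il13, Penk, Zfp36l2, Tsc22d2 and Hspa1b turned in sign in at least 1 of these draws. Of the proliferation list 1 to 6 genes passed in these draws, and of the chemokine list 0 to 3. Splitting the same cells on 20 autosomal panels of matched level called 0 to 108 genes (median 6.5), and 6 panels called at least 17. The proliferation medians of these panels ran from -1.02 to 0.58, against 0.61 for the Y genes and 0.46 to 1.05 in their further draws. The panels were not drawn again, and the one at -1.02 held the tubulin gene Tubb4b.

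In CD8 T cells, the larger gate, some cell division genes were again among those higher in Y-null cells. The Y-null share differed between the T-like clusters in which most cells had a Cd8a UMI. At 10000 UMIs it was 14.8% and 20.975% (libraries 1 and 2) in the cluster led by Gzma. It was 6.45% and 13.2% in that led by Gzmf, 10.4% and 21.4% in that led by Gzmb, and 6.78% and 10.8% in that led by Xcl1. Null and positive cells may therefore come from these clusters in different proportions, which was not tested. Hmgb2 was higher in Y-null CD8 T cells by 0.23 (SE 0.0360, adjusted p = 2.24e-07 in edgeR), and the chemokine Xcl1 (ENSMUSG00000026573) by 0.68 (SE 0.0905, adjusted p = 2.92e-10 in edgeR). The sums held 1106 and 1282 null and 900 and 757 positive cells, and 113 genes were higher and 42 lower among 9383 tested. The proliferation marker Mki67 was higher by 0.32 (SE 0.0840), the ubiquitin ligase partner Ube2c by 0.34 (SE 0.0885), Stmn1 by 0.28 (SE 0.0606), the histone gene Hist1h2ae by 0.39 (SE 0.0770), the replication licensing inhibitor Gmnn by 0.50 (SE 0.117), and the spindle and chromosome genes Tpx2 by 0.49 (SE 0.138), Hmmr by 0.66 (SE 0.170) and Ncapd2 by 0.62 (SE 0.155). Among granzymes, Gzma was higher by 0.28 (SE 0.0612), Gzmc by 0.35, Gzmd by 0.61 and Gzmf by 0.30, but each turned in sign in at least 1 further draw of the thinning, with lowest values of -0.06, -0.26, -0.05 and -0.27. The glycolysis genes Ldha (0.17), Gapdh (0.13) and Eno1 (0.26) were higher as well. The quiescence factor Bach2 was lower at -0.36 (SE 0.0852), Ikzf2 at -0.17, the phosphatase gene Ptprk at -0.69, Aff3 at -0.90, Galnt18 at -0.85 (0.0019 when thinned to 1000 UMIs) and Slc9a9 at -0.45. The libraries differed for Xcl1 (0.33 in library 1 and 0.85 in library 2), Gzmc (0.21 and 0.70), Gzmd (0.39 and 1.29), Gzmf (0.05 and 0.79), Ube2c (0.45 and 0.22) and Aff3 (-0.16 and -1.19). Proliferation genes were higher in 6 of 22 with none lower (14 adjusted over the list alone), with a median of 0.25 (camera, adjusted p = 7.31e-17; adjusted p = 0.749 with an estimated correlation). Cytotoxic genes were higher in 5 of 17 with none lower (5 and 1 adjusted over the list alone; median 0.07), hypoxia and glycolysis genes in 3 of 17 (5 adjusted over the list alone; median 0.08), and oxidative phosphorylation genes in 1 of 19 (6 adjusted over the list alone; median 0.12). Checkpoint receptor genes had a median of -0.12 with none of 17 passing (2 lower adjusted over the list alone; camera, adjusted p = 0.00811; adjusted p = 0.749 with an estimated correlation). In total 5 lists passed camera here at the preset correlation, and 0 with an estimated one.

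The CD8 calls, too, depended on the fit. DESeq2 called 0 genes, with 82 at an unadjusted p under 0.05, a fit without the library block called 0 with 108, and edgeR with the block had 1114 at that level. In 5 further draws 127 to 311 genes were called, 38 to 95 of them among the 155, and Hmgb2, Hist1h2ae, Mki67, Ube2c and Stmn1 passed in every draw, Xcl1, Gzma, Ldha and Bach2 in 4, and Gzmd, Ncapd2 and Ikzf2 in 0. Over these draws 10 to 14 proliferation, 1 to 5 cytotoxic, 1 to 4 hypoxia and glycolysis and 2 to 6 oxidative phosphorylation genes passed. Of 20 matched panels, 1 called at least as many genes (2 to 169, median 10.5) and 1 gave a proliferation median as high as 0.25. The medians of these panels, which were not drawn again, ran from -0.47 to 0.34, and those of the Y genes in the further draws from 0.34 to 0.45. The panel at -0.47 held the spindle gene Tpx2. A cytotoxic median as high came from 8 of the 20 panels, an oxidative phosphorylation median as high from 2 and a checkpoint receptor median as low from 1. Splitting CD8 T cells on the 4 X homologues, a test added after the data were seen, called 154 genes, 77 of them among the 155.

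**Figure D5:**
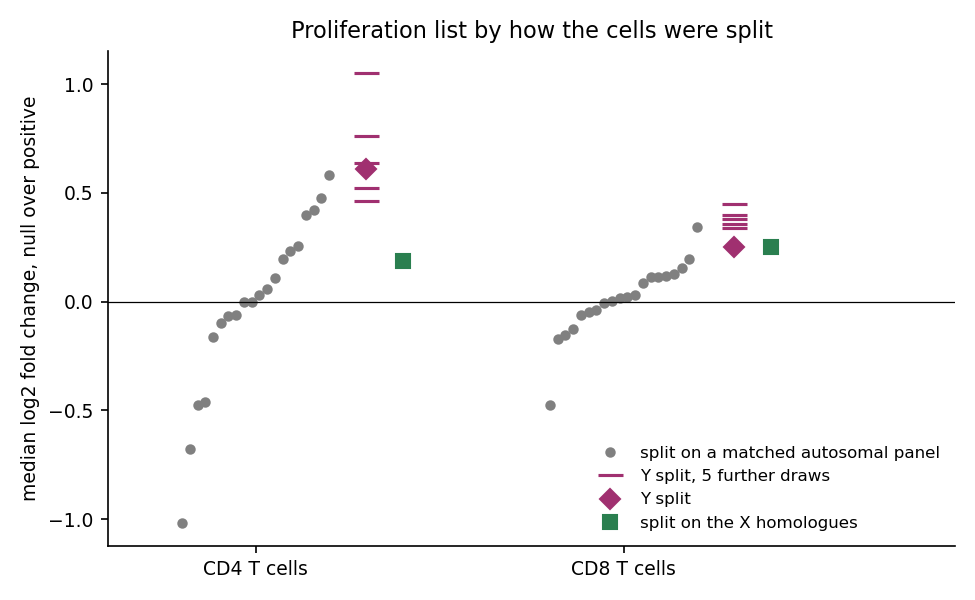
Median log2 fold change of the proliferation list, null over positive cells, for splits on the Y panel (diamond, with 5 further draws as dashes), on 20 matched autosomal panels (grey points) and on the 4 X homologues (square), in CD4 and CD8 T cells. The Y split lies at 0.61 in CD4 and 0.25 in CD8 T cells, and the panels reach 0.58 and 0.34. Only the Y split was drawn again.

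Whether the Y-null and Y-positive cells differed otherwise in CD4 than in CD8 T cells was tested as an interaction. No gene of 8858 passed in edgeR, with 414 at an unadjusted p under 0.05. The fit had a library term but none for library by gate. Differences between the libraries that were not the same in both gates thus entered its spread. A result without calls therefore does not show that Y status had the same effect in both gates. DESeq2 called 0 genes with 86 at that level, and a fit without the library block 0 with 208, while edgeR without a filter on low counts called 2 of 17248. The Foxp3-positive share of Y-null and Y-positive CD4 T cells differed in opposite directions in the 2 libraries. Foxp3 was seen in 39.4% (32.9% to 46.1%) of 221 null and 34.0% (27.4% to 41.2%) of 194 positive cells in library 1, and in 32.5% (25.2% to 40.5%) of 154 null and 34.9% (27.2% to 43.3%) of 146 positive cells in library 2. The difference was 1.44 points on average (SD 5.52, n = 2 libraries). At 1000 UMIs it was 11.1 points in library 1, above the highest of the matched panels (7.48), and -6.12 points in library 2, and at 5000 UMIs it was 7.11 and 1.92 points.

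Tumour-like cells were compared with macrophage- and monocyte-like cells because fibroblast-like cells numbered only 8 in library 2, and fixed list genes, which took no part in the clustering, are reported. Macrophages carried more antigen presentation, chemokine and interferon response genes, while matrix and hypoxia genes went both ways. The matrix glycoprotein Sparc (ENSMUSG00000018593) was higher in tumour-like cells by 8.59 (SE 0.183), and the invariant chain gene Cd74 (ENSMUSG00000024610) lower, at -6.43 (SE 0.175, adjusted p = 2.06e-279 in edgeR). Of 296 list genes tested, 78 were higher and 162 lower in tumour-like cells, and 239 of these 240 had the same sign in both libraries. The latent TGF-beta binding protein Ltbp1 was higher by 8.15 (SE 0.235), the myeloid growth factor Csf2 by 7.70 (SE 0.183), the transcription factor Gata3 by 5.27 (SE 0.205), S100a4 by 4.76 (SE 0.147) and the hypoxia-induced carbonic anhydrase Car9 by 3.99 (SE 0.137). Vim (2.68), Zmat3 (2.19), Capg (2.14), Zeb1 (2.12), the interferon-induced Bst2 (1.88) and the hypoxia sensor Egln3 (1.47) were also higher. Snai2 had 3 UMIs in macrophages and a ratio of 167 (56.2 to 821), Ido1 had 1 and a ratio of 94.6 (15.7 to 3864), and Nectin3 had 1 and a ratio of 480 (84.7 to 19068). In macrophages the matrix protein Tgfbi (-8.86, SE 0.206), the cytokines Il6 (-8.57, SE 0.263) and Tnf (-7.45, SE 0.207), and the chemokines Cxcl9 (-7.57, SE 0.193), Ccl4 (-7.06, SE 0.174) and Ccl8 (-6.51, SE 0.204) were higher than in tumour cells. The immune regulators Vsir (-6.98), Entpd1 (-6.96) and Pdcd1lg2 (-6.19) and the immediate early gene Atf3 (-7.82) went the same way. The costimulatory ligand Cd86 had 3 UMIs in tumour-like cells and was higher in macrophages by a ratio of 2658 (909 to 12890), and Cxcl14 and P4ha2, with none there, were at least 28.8-fold and 22.9-fold higher.

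Antigen presentation set these classes apart. All 7 MHC class II genes were lower in tumour-like cells (median -5.77; camera, adjusted p = 2.82e-05; adjusted p = 0.740 with an estimated correlation), among them H2-Ab1 (-6.65) and its activator Ciita (-5.77). MHC class I genes were lower in 11 of 15 and higher in 2 (median -0.65), such as Psmb8 (-4.92) and H2-Q7 (-2.86). Interferon response genes were lower in 19 of 25 and higher in 2 (median -2.04), such as Cxcl10 (-4.80) and Gbp5 (-5.28). Chemokines were lower in 16 of 19 and higher in 3 (median -4.80), and checkpoint receptors lower in 13 of 16 with none higher (median -2.37). Hypoxia and glycolysis genes were higher in 12 of 20 and lower in 6, with a median of 0.40 and a mean of -0.26, and camera gave no call (adjusted p = 0.202). Oxidative phosphorylation genes were higher in 12 of 19 with none lower (11 adjusted over the list alone). Proliferation genes split into 8 higher, such as Ccnb2 (0.89, with library values of 1.13 and 0.57), and 10 lower, such as Mki67 (-0.82, with -0.50 and -1.24), with a median of -0.17. For T helper genes the median (-0.51) and the mean (0.67) differed in sign, as they did for the matrix list (-0.04 and 0.19, with 7 higher and 8 lower), and neither was called. The Y panel was lower in tumour-like cells in all 4 genes, from -6.18 for Uty to -4.62 for Kdm5d, and of the X homologues Kdm6a (-1.31), Ddx3x (-1.19) and Kdm5c (-0.88) were lower too. In all, 6 lists passed camera at the preset correlation and 0 with an estimated one.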

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

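Chosen only after the results were seen were the depths of 10000 and 20000 UMIs, panels matched within a library, null shares of single libraries, the split on X homologues, the fit on cells without proliferation UMIs, the further draws, the deeper tumour-like cluster, the unnamed cluster and the Y level with doublets kept. Of the values of the main results with both libraries kept, 49 stayed within 1 SD between libraries (counts of genes: within 1.5 times; Y level: all 4 genes passing) and 43 moved further. For the called genes named in the text, outside the split on X homologues and the fit on cells without proliferation UMIs, 672 values with both libraries and the main draw kept direction and call, 231 kept the direction without passing (63 of these with DESeq2 and 57 without the library block), and 4 turned in sign. In the further draws 225 kept both, 109 kept the direction without passing and 14 turned. With a library left out, where nothing could be tested, 327 kept the direction and 1 turned. The cause was not tested for any that moved or turned.

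The counts listed next moved by over 1.5 times, except that every further draw and both splits on X homologues are given. With DESeq2 the genes called numbered 2515 for CD4 against CD8 T cells, 0 and 0 for Y status in CD4 and CD8 T cells and 25 for Foxp3 status. Without the library block they numbered 2072, 0, 0 and 59 in the same order. Without a filter on low counts, Y status in CD8 T cells gave 48 genes and the interaction of Y status and gate 2. Keeping doublets gave 109 genes for Y status in CD4 T cells. Thinning to 1000 UMIs gave 0 genes in CD4 and 76 in CD8 T cells, and thinning to 5000 UMIs gave 124 and 277. A Y status at 2 UMIs gave 2 and 457. Splitting CD4 T cells on the X homologues gave 29, and splitting CD8 T cells on them 154. In cells without a proliferation UMI Y status gave 4 genes in CD4 and 0 in CD8 T cells, with 50 and 235 at an unadjusted p under 0.05, from 1189 and 3022 genes tested. The 5 further draws of the thinning gave 48, 78, 4, 15 and 85 genes in CD4 T cells, 311, 176, 286, 127 and 298 in CD8 T cells and 234, 265, 141, 285 and 343 for Foxp3 status. With an estimated correlation, the lists past camera fell to 0 in all 5 comparisons, from 12 for CD4 against CD8 T cells, 3 and 5 for Y status, 6 for Foxp3 status and 6 for tumour-like cells.

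The difference in Y-positive share between T-like and tumour-like cells was 23.4 points at 1000 UMIs, 68.0 at 5000 UMIs and 79.9 without thinning. It was 31.1 points without Ddx3y, 33.7 without Eif2s3y and 25.8 without Uty. The excess of Y-null macrophages over matched panels was 7.58 points at 5000 UMIs (4.04 and 11.1 in libraries 1 and 2), 7.62 at 10000 UMIs (5.19 and 10.0) and 6.17 at 20000 UMIs (3.52 and 8.81), and that of CD4 T cells 6.30 points at 10000 UMIs (2.35 and 10.3, reached by 54 and 2 of 200 panels).

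With n = 2 libraries, a value without 1 of them cannot lie further than 1 SD from their mean, so ranges are given. They were 5.16 to 5.40 for the Y panel's mean log2 fold change and 37.2 to 43.7 points for the Y-positive share. The T-like share ranged from 51.6% to 61.9% with the shallow cluster left unnamed. The Y-null excess ranged from -0.648 to 4.41 points in CD8 T cells, from -0.333 to 5.06 in CD4 T cells and from 0.0590 to 4.64 in macrophages, and the Foxp3 difference from -2.46 to 5.35 points, so the CD8, CD4 and Foxp3 values turned in sign. Counts of genes could not be tested without a library, since no residual degree of freedom is left. The Y level comparison and the tumour-like list genes stayed within their bounds in every alternative run. Outside the further draws, those that turned were Hbb-bt, at 0.55 for CD4 against CD8 T cells with the unnamed cluster included, Tsc22d2 at 0.17 and Galnt18 at 0.0019 for Y status at 1000 UMIs, Hspa1b at 1.01 for Y status at 5000 UMIs, and Cxcl2, which ranged from -0.0249 to 2.16 for Foxp3 status with a library left out. In the further draws, for Y status in CD4 T cells, Hspa1b turned to 1.54 and 2.08, Tsc22d2 to 0.1896 and 0.0020, Zfp36l2 to 0.12, Penk to -0.40 and -0.48, Il13 to -1.19 and Cenpf to -0.19, and in CD8 T cells Gzma turned to -0.0568, Gzmf to -0.2677, Gzmc to -0.2563 and Gzmd to -0.0485 and -0.0543. Changes were simulated at the depth and cell numbers of these data, with the dispersion set at 0.01. Of 2-fold changes, 27.6% were recovered for Y status in CD4 T cells and 41.8% for Foxp3 status. In the other 3 comparisons simulated the share was 66.7% to 71%. The dispersion was not estimated from the data, so these shares hold for that setting only.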

Other observations

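Of the tests in this part, the panel comparisons at 20000 UMIs, the keratin test, the panel test of the proliferation list and the splits on X homologues were chosen only after the results were seen.

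Checkpoint genes were spread over different cell classes. Among T cells, Pdcd1 stood at 354 CPM in CD8 and 170.3 CPM in CD4 T cells (means of both libraries), Lag3 at 271 and 161 CPM, and Havcr2 at 177 and 105 CPM. Ctla4 (1503 and 441 CPM) and Tigit (49.4 and 21.4 CPM) were higher in CD4 than in CD8 T cells, and Tox was near level at 517 and 491 CPM. Havcr2 was highest in dendritic-like cells, at 371 CPM, and so was Btla at 318 CPM. The ligand Cd274 was highest in neutrophil-like cells at 1994 CPM, followed by macrophage- and monocyte-like cells at 298 CPM, and reached only 9.08 CPM in tumour-like cells. Tumour-like cells had the highest Lgals3 (2116 CPM) and Cd276 (47.4 CPM) of the 6 groups.

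Chemokine genes also divided by class. Neutrophil-like cells carried Cxcl2 at 48499 CPM, Ccl4 at 10209 CPM, Ccl3 at 9236 CPM and Cxcl3 at 5290 CPM. Macrophage- and monocyte-like cells had the highest Cxcl9 (475 CPM), Cxcl10 (683 CPM), Ccl2 (578 CPM) and Il6 (119 CPM) of the 6 groups. Ccl5 was highest in CD8 T cells at 1699 CPM, and the antigen presentation gene Cd74 in dendritic-like cells at 12450 CPM. Neutrophil-like cells also led for Entpd1 (1338 CPM), the glucose transporter Slc2a1 (517 CPM), Vegfa (389 CPM) and Isg15 (1311 CPM).

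Some macrophages and CD8 T cells had no Y panel UMI even when read at 20000 UMIs. For macrophages, at most 3 of 200 panels matched within a library reached the null share, which argues against counting depth. The null cells were 24.7 times (15.1 to 38.2) and 25.0 times (18.6 to 32.8) as many as Poisson counting at each cluster's Y level would give, in libraries 1 and 2. That argues against differences in Y level between clusters, but cells of lower Y level within a cluster were not tested for. Poisson counting gave 0.809 null cells of 454 and 2.04 of 522, below the panel medians of 0.881% and 0.958%. These ratios do not by themselves show a loss either. Krt8 and Krt18 reached at most 0.546% of the tumour-like level in the null cells, which argues against misplaced tumour cells. The keratin ratio of null to positive macrophages, named for this test at first, was 2.17 and 0.839 from 1 UMI in each library and decided nothing. In CD8 T cells of library 1, 21 of 200 panels reached the null share, so counting depth may account for it, while in library 2 only 1 did and the null cells were 3.75 times (2.83 to 4.88) those that counting by cluster gives. That ratio was 3.45 in library 1 too, where panels did reach the null share, so it does not by itself show a loss. Before thinning, the null cells had median depths of 26111 to 32633 UMIs, and their UMIs beyond 20000 were not read for Y genes. Whether null cells lack the chromosome, do not transcribe it or transcribe it at a low level stays open. No biological explanation was tested.

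The median log2 fold change of the proliferation list, Y-null over Y-positive cells, was above 0 in both gates (0.61 in CD4 and 0.25 in CD8 T cells), though only 5 of 20 and 6 of 22 genes passed and camera with an estimated correlation gave no call. A split on any genes of that level and one on the Y genes cannot be told apart here. Only the Y split was drawn again, so its medians in 6 draws were set against panel medians of the main draw. As far from 0 as these Y medians were 0 to 5 of 20 matched panels in CD4 and 1 to 2 of 20 in CD8 T cells. In the main draw, the 2 CD4 panels as far from 0 lay below it, at -0.68 and -1.02, and both held the tubulin gene Tubb4b. The CD8 panel furthest from 0 (-0.47) held the spindle gene Tpx2. The panels left out genes of the fixed lists only, so other cell division genes could enter them. Whether such genes moved these medians was not tested. For that reason, and with panels from the main draw only, the test cannot decide. A trait that the Y genes share with their X homologues may account for it in CD8 T cells. There the X split gave 1.00 times the median of the Y split, with 1.24 and 0.634 in libraries 1 and 2. The Y median used (0.25) was below those of the further draws (0.34 to 0.45), against which the ratio would be lower. In CD4 T cells that ratio was 0.303, with 0.1197 and 0.590 in the libraries. The spread between the libraries is why a shared trait and a Y effect cannot be told apart there. Y-null shares also differed between the clusters of mostly CD8 T cells, and whether that gives the CD8 median was not tested. No biological explanation was tested.

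Tumour-like cells had 53 and 20 Y panel UMIs although the line has lost Y. Free RNA of host cells may account for them, since host markers in tumour-like cells predicted 0.691 times the observed Y level in library 2 and 1.32 times in library 1. For tumour and host cells caught together, host markers were 4.05 and 6.37 times higher in tumour-like cells with a Y UMI than in those without, between the bounds set for and against, and the cells with a Y UMI were also deeper (median 52785 against 27270 UMIs in library 1). Free RNA and joint capture therefore cannot be told apart for these UMIs. No biological explanation was tested.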
